A study of Mus musculus with 6 samples.

How the data were processed

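RNA was measured in 6 samples labelled as whole mouse embryo, of the C57BL/6N strain at embryonic day 9.5, 3 wild type and 3 homozygous for a knockout of Lphn2. Per the labels' protocols, RNA was extracted with Trizol and 500 ng of total RNA per sample went into the Lexogen QuantSeq kit, which reads tags from the 3' ends of polyadenylated transcripts. The deposited values are whole-number counts per gene symbol, 1 table per sample, with 24421 symbols in each. Per the submitters' processing notes, Bowtie2 and edgeR were used and the genome build was mm10. Their versions and roles, the gene annotation, the counting program and its handling of strand and of reads that match several places are not given in the sources used here. The authors deposited the counts without normalization, since the totals differed between samples.

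The deposited counts carried traces of how they were made. Of 11680 genes with at least 10 counts in all 6 samples, 2330 (19.9%) had 6 counts that shared a divisor above 1. This held for 1.92% of 5587 genes with 1 annotated transcript and for 38.5% of 5553 genes with several. The divisor equalled the number of annotated transcripts in 1528 of the 2138 genes of the second kind. A further 128 symbols had the same counts in all 6 samples as at least 1 other symbol, over symbols with a total above 50. Where a count is a multiple of the tags observed, its counting error is larger than the count shows. Genes that share reads with a near-identical copy are reported as uncertain. No row was without a gene name, and 5633 symbols had 0 counts in all 6 samples.

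Groups were taken from the genotype labels. The labels do not say whether each sample came from 1 embryo, nor from which litters, so p-values measure the spread between these samples, which may in part be technical. Each sample description carries a code of 2 numbers whose meaning is not stated, and the first number is 32 for wild type replicate 1 and 45 for the other 5 samples. If it marks a litter or batch, 1 of these holds 1 sample, so groups cannot be compared within it. The comparison within the other is the one without wild type replicate 1. No pair of samples agreed within sampling noise: chi-square divided by its degrees of freedom lay between 23 and 296 over genes with at least 20 counts in the pair. Total counts were 26700584, 18352150 and 36213611 in wild type replicates 1, 2 and 3 and 23887717, 15275299 and 14476809 in knockout replicates 1, 2 and 3.

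Genes were kept with filterByExpr of edgeR 4.0.16 (minimum count of 10), which left 13848, and libraries were scaled by TMM. The knockout was compared with wild type by the quasi-likelihood test of edgeR with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Levels are given as TMM-normalised CPM, counts relative to the effective library size on the scale of the cpm function of edgeR, as mean ± SD of 3 samples per group, and fold changes as log2 of knockout over wild type with their standard errors (SE). Gene lists were tested with camera of limma 3.58.1, with its preset correlation between genes of 0.01, on log2 CPM with a prior count of 2. Lists with at least 3 tested members entered, two-sided, and p-values were adjusted over lists. The medians of lists were the same to 2 decimals with members at 0 counts in 1 group set to a bound from 3 counts. Beside it, camera with a correlation estimated from these samples, camera on ranks, and fry were run. Fry asks whether the genes of a list move one way on balance or, as its mixed test, in either direction, and compares a list with no other genes. Of 44 lists, the mitochondrially encoded genes had no symbol in the tables and the X inactivation list had 2 tested members, so 42 lists were tested. Gene positions come from GENCODE M21 on mm10, matched by symbol, and 24001 of 24421 symbols had one. Computation used R 4.3.3, and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

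The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names Adgrl2 first, in every sample. It then names up to 15 genes per direction that pass the threshold, have all 3 knockout values on 1 side of all 3 wild type values and average at least 5 CPM, ranked by fold change and leaving out symbols of predicted genes. Where fewer than 5 genes pass in a direction, it names the 5 with the smallest p as not past the threshold. For each list it names up to 4 passing members or, with none, the 2 members with the smallest p, as values. All measured latrophilins and ligands are named, and Y-linked and X inactivation genes are given per sample. Genes named outside the rule are said to be so. 1 gene that the rule names is not reported here.

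Alternatives were other scaling factors (DESeq2 size factors, upper quartile, library size only), no filter, a filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, removal of X, Y, extraembryonic and decidual list genes, and each sample left out in turn. Added after seeing the data were counts divided by their common divisor, removal of Rn45s, 1 symbol per set with identical counts, and knockout replicate 1 alone against wild type. Outlier tests were not made, since groups of 3 are too small for them.

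The tests were tried on simulated data for the knockout against wild type comparison, drawn from the means and library sizes of these samples. Over 13511 genes, edgeR called 0 of 67 genes changed 2-fold, 27 of 67 (40.3%) changed 4-fold and 51 of 66 (77.3%) changed 8-fold, along with 6 of 13315 unchanged genes. The 13511 are the simulated genes that passed the filter, and changed genes that did not pass it are included in the denominators as not called. Over 13505 genes, camera found a list of 15 genes raised 2-fold and called 0 of 40 unchanged lists. Genes were simulated independently of each other and the lists drawn at random, so this trial did not test lists whose members move together. In the lists called below, the correlation estimated from these samples ranged from 0.11 (immediate early) to 0.906 (trophoblast), against the preset of 0.01.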

Results

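Transcript levels were measured with 3' end tags in samples labelled as whole mouse embryo at embryonic day 9.5. At this stage the looped heart tube beats and its chambers begin to form. The 6 libraries comprised 3 labelled wild type and 3 labelled homozygous for a knockout of Lphn2. This gene encodes latrophilin-2, an adhesion G protein-coupled receptor now named Adgrl2. The series names this receptor as a surface marker of cardiac progenitors with a role in the developing heart, and the comparison asks which transcripts differ in the embryo that lacks it. Total counts ranged from 18352150 to 36213611 in wild type and from 14476809 to 23887717 in knockout libraries, with 14880 to 17322 gene symbols above 0. Rn45s, the ribosomal RNA precursor, took 9.53 ± 1.71% of wild type and 10.5 ± 2.05% of knockout counts.

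Adgrl2 (ENSMUSG00000028184.12, mm10 chromosome 3, 148815583 to 148990555, minus strand) was read at 10.9, 7.56 and 15.96 CPM in wild type replicates 1, 2 and 3 and at 5.49, 1.67 and 2.78 CPM in knockout replicates 1, 2 and 3. Every knockout value lay below every wild type value, with means of 11.5 ± 4.24 and 3.31 ± 1.97 CPM (SD, n = 3 each). The log2 fold change was -1.78 ± 0.50 (SE), and the difference did not pass the threshold over all genes (edgeR quasi-likelihood test, adjusted p = 0.194). It passed with DESeq2 (adjusted p = 0.0224) and without knockout replicate 1 (adjusted p = 0.0442), within a range of 0.0224 to 1.0 over the alternatives. The labels do not say which part of the gene was deleted, and tags from the 3' end of the transcript can lie outside it, so these values do not check the genotype labels.

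Among the other latrophilins and their ligands, Adgrl4, an endothelial relative, stood at 33.1 ± 11.96 CPM in wild type and 71.7 ± 24.2 CPM in knockout libraries (log2 fold change 1.11). Flrt3, which encodes a transmembrane ligand of latrophilins, stood at 19.6 ± 17.96 and 3.22 ± 2.86 CPM (-2.58). Adjusted over the list alone, Adgrl2 and Flrt3 were lower and Adgrl4 was higher, against 0 of the 7 tested members over all genes. Adgrl1, Flrt2, Tenm3 and Tenm4 had log2 fold changes of -0.46, -0.71, -0.75 and -2.01, none past a threshold. The first 3 of these turned positive without wild type replicate 3, at 0.40, 0.20 and 0.0011. Adgrl3, Flrt1, Tenm1 and Tenm2 were too low to be tested. As a list the family did not pass (median -0.75, camera adjusted p = 0.308), except without wild type replicate 2 (adjusted p = 0.00823, range over the alternatives 0.00823 to 0.925).

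The libraries differed in the tissues whose markers they held. Tpbpa, a marker of the spongiotrophoblast of the placenta, was read at 170.3, 206 and 36.4 CPM in wild type replicates 1 to 3, and at 64.7, 0.400 and 2.00 CPM in knockout replicates 1 to 3. Prl3b1, placental lactogen II, stood at 51.8 ± 44.3 CPM in wild type and 4.59 ± 7.77 CPM in knockout libraries. Over the 16 tested trophoblast genes, the median difference from the wild type mean was 0.55 in knockout replicate 1, -5.52 in replicate 2 and -4.81 in replicate 3 (log2). The list fell in the knockout group (median -1.15, 16 of 16 lower, camera adjusted p = 0.000169; adjusted p = 0.564 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. With knockout replicate 1 alone against wild type the list turned upward (adjusted p = 0.0472, range over the alternatives 1.98e-10 to 0.564).

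Decidual genes, which mark the maternal lining of the implantation site, were among the most abundant transcripts. Prl8a2, decidual prolactin-related protein, averaged 20572 ± 7235 CPM in wild type and 3171 ± 2042 CPM in knockout libraries (log2 fold change -2.70 ± 0.54 SE, adjusted p = 0.166). Erv3, placed on the decidual list, stood at 2479 ± 856 and 282 ± 201 CPM (-3.14, adjusted p = 0.165). Every knockout library lay below every wild type library for both genes. Wild type and knockout libraries alike thus held transcripts of the maternal lining in abundance, so a difference between the groups need not lie in the embryo. Of the 14 decidual genes, 4 were higher and 4 lower adjusted over the list alone and 0 in either direction over all genes. The list as a whole had no called direction (median -0.52, camera adjusted p = 0.454), while its members differed in one direction or the other by the mixed test of fry (adjusted p = 0.00302).

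Yolk sac genes, which serve nutrition of the early embryo, fell as a list. The visceral endoderm list had a median log2 fold change of -2.48 over 22 genes, 20 of them lower (camera adjusted p = 3.23e-07; adjusted p = 0.564 with an estimated correlation), with 0 past the threshold over all genes and 0 adjusted over the list alone. Trf, transferrin, stood at 98.97 ± 57.03 CPM in wild type and 25.6 ± 8.86 CPM in knockout libraries, and Serpina1a, an alpha-1 antitrypsin, at 7.09 ± 8.79 and 0.201 ± 0.243 CPM. The list median lay at -0.93, -5.86 and -5.63 from the wild type mean in knockout replicates 1, 2 and 3. In replicate 1 it thus lay below that mean, where the trophoblast median lay above it. With knockout replicate 1 alone against wild type the yolk sac list was called lower (adjusted p = 3.21e-06, range over the alternatives 2.94e-14 to 0.564). Knockout replicates 2 and 3 were also the closest pair of libraries across genes (r = 0.961, genes not being independent replicates). On the first principal component, with 54.1% of the variance, they scored 99.7 and 88, and the other libraries -73.6 to -14.3. Knockout replicate 1 had r of 0.956, 0.942 and 0.897 with wild type replicates 1, 2 and 3. With knockout replicates 2 and 3 it had r of 0.909 and 0.913. It thus lay closer to wild type replicates 1 and 2 than to the other knockout libraries.

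**Figure D1:**
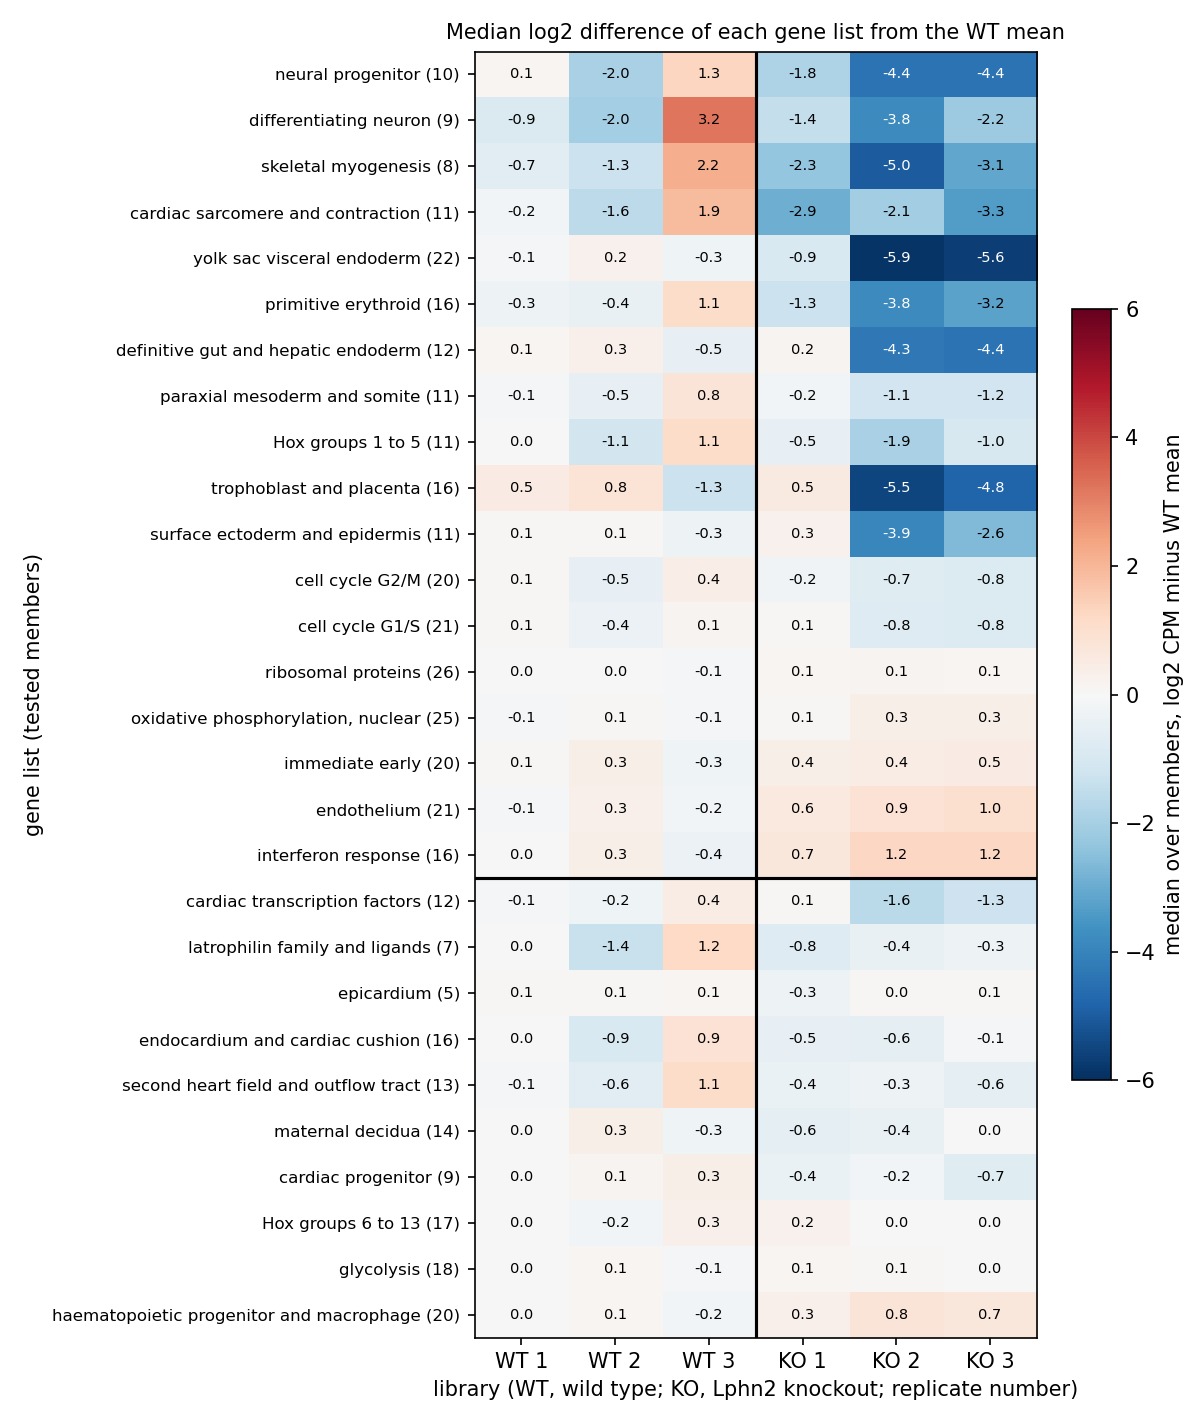
Median log2 CPM of gene lists in each library (columns), as the difference from the wild type mean, with the number of tested members in parentheses. The 18 lists above the black line passed camera with its preset correlation. Those below it are some of the lists that did not. Trophoblast medians lie at -5.52 and -4.81 in knockout replicates 2 and 3 against 0.55 in replicate 1, and the interferon list is higher in all 3 knockout libraries.

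Of 13848 genes tested one by one, 7 symbols were lower and 0 were higher in the knockout (edgeR, adjusted p under 0.05). Limma-voom gave 7 lower and 0 higher and DESeq2 488 lower and 439 higher, while 950 and 1202 genes had an unadjusted p under 0.05 in edgeR. Groups did not overlap in 1678 genes with all knockout values above and 1300 with all below, 21.5% of those tested against 10% by chance. The 7 symbols were 4 distinct sets of counts. Ccl27b (mm10 chromosome 4, 42655251 to 42656005), a skin-homing chemokine gene, fell from 261 ± 49.4 to 46.5 ± 8.78 CPM (log2 fold change -2.49 ± 0.23 SE, adjusted p = 0.0312). Il11ra2 (chromosome 4, 42656355 to 42661893), which encodes an interleukin-11 receptor alpha chain, fell from 99.98 ± 17.2 to 22.5 ± 3.59 CPM (-2.15 ± 0.21 SE, adjusted p = 0.0313). Mxd1 (chromosome 6, 86647042 to 86669161), a partner of Max that opposes Myc, fell from 38.4 ± 4.74 to 10.3 ± 1.25 CPM (-1.90 ± 0.20 SE, adjusted p = 0.0488).

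Ccl27b and Il11ra2 belong to a multicopy cluster on chromosome 4 whose members share reads, so their values are uncertain as to which copy they came from. The remaining symbols, named after their values were seen, were Gm13306 and LOC100861978, with the counts of Ccl27b, Gm2002, with the counts of Il11ra2, and Gm2506. All 6 moved as 1 across libraries (lowest r = 0.9998). The related Ccl27a and Il11ra1 nearby, also named after their values were seen, stood at 539.7 ± 93.5 against 276 ± 35.5 CPM (-0.97, adjusted p = 0.166) and 1222 ± 161 against 1059 ± 108 CPM (-0.21, adjusted p = 0.619). With 1 symbol kept per identical set no gene passed, with adjusted p = 0.0626 for Ccl27b (range over the alternatives 7.75e-21 to 0.793) and 0.0853 for Mxd1 (2.85e-11 to 1.0), which also missed it with limma-voom (0.0555), library size as the only scaling (0.0614), the common divisor removed (0.0525) and without wild type replicate 2 (0.1) or 3 (0.0571). Il11ra2 missed it without wild type replicate 2 (adjusted p = 0.0534, range over the alternatives 1.22e-15 to 0.832). The count of lower genes was 0 without wild type replicate 1, knockout replicate 2 or knockout replicate 3, 11 without wild type replicate 2, among which 4 of the 7 symbols remained, and 466, beside 252 higher, without knockout replicate 1.

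The 5 genes with the smallest p among those higher in the knockout did not pass the threshold. Kazald1, a secreted protein with an insulin-like growth factor binding domain, stood at 23.4 ± 3.63 CPM in wild type and 59.2 ± 1.91 CPM in knockout libraries (log2 fold change 1.34 ± 0.18 SE). Batf, a lymphocyte transcription factor, stood at 4.11 ± 0.376 and 15.4 ± 2.65 CPM (1.91), and Ptprr, a protein tyrosine phosphatase, at 7.18 ± 1.44 and 28.5 ± 6.64 CPM (1.98). Atp8b2, a phospholipid flippase, stood at 18.3 ± 2.11 and 45.3 ± 4.62 CPM (1.31), and Tlr3, the receptor for double-stranded RNA, at 17.1 ± 2.02 and 56.1 ± 14.9 CPM (1.72). The adjusted p was 0.112 for the first 4 and 0.118 for Tlr3. All 5 passed with DESeq2 and without knockout replicate 1, where Kazald1 had adjusted p = 8.43e-07 and adjusted p = 0.0276 (range over the alternatives 8.43e-07 to 1.0).

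**Figure D2:**
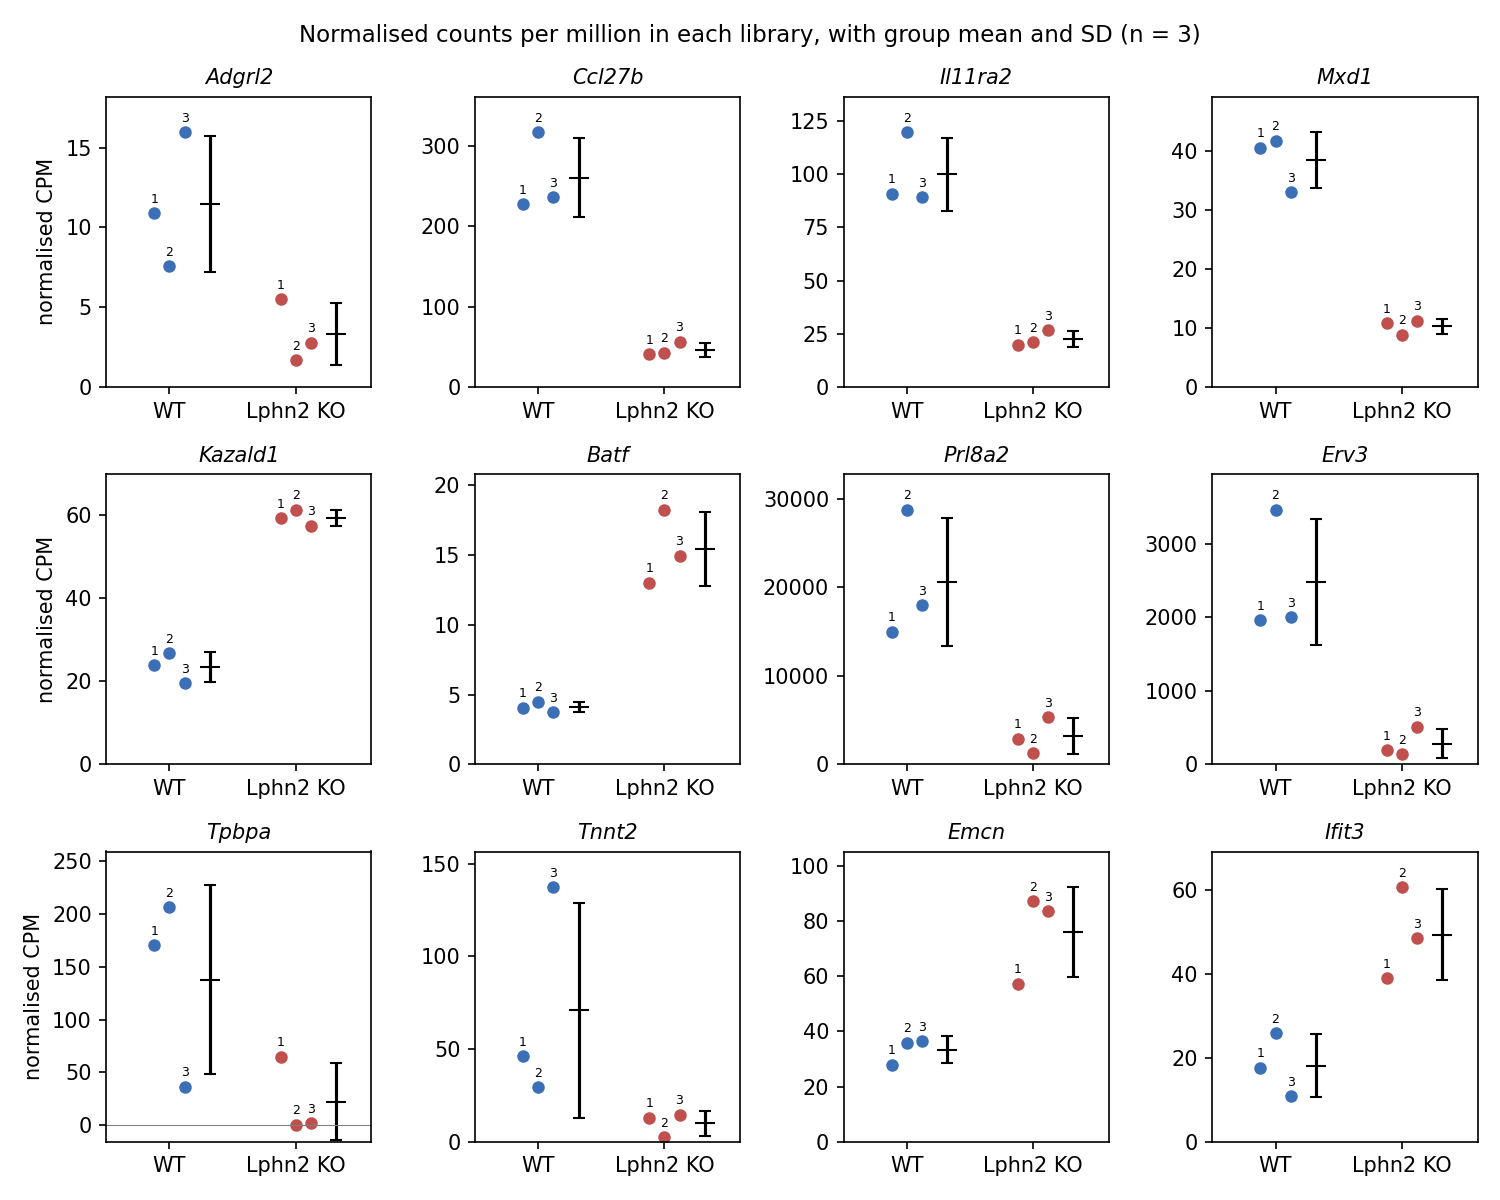
TMM-normalised CPM of 12 genes in each library (points, numbered by replicate; blue, wild type; red, Lphn2 knockout), with the group mean and SD (black, n = 3). Ccl27b, Il11ra2 and Mxd1 passed the threshold over all genes and the others did not, and Tpbpa is at 0.400 and 2.00 CPM in knockout replicates 2 and 3.

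Of the 42 gene lists tested, 5 rose and 13 fell with camera at its preset correlation, as described list by list in what follows. Lists share members, so these calls are not independent of each other. Actc1 stands on the sarcomere and myogenic lists, and Sox17 on the endothelial, yolk sac and gut lists. Krt8, Krt18 and Epcam were placed on both the gut and the surface ectoderm list. With an estimated correlation 0 lists were called in either direction and 0 had an unadjusted p under 0.05, and fry by direction called 0, with 6 higher and 4 lower at an unadjusted p under 0.05. The mixed test of fry called 9 lists after adjustment. The 5 lists higher became 3 without wild type replicate 3. The 13 lower became 20 without wild type replicate 2, 8 with a filter of at least 5 CPM in 3 libraries and 7 with knockout replicate 1 alone. That filter ended the lower calls of the neuronal, myogenic and gut lists (adjusted p = 0.0779, 0.221 and 0.173) and the higher call of the ribosomal list (0.163). It left the paraxial mesoderm list and Hox groups 1 to 5 with fewer than 3 tested members, so these were not tested there.

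Genes of the cardiac contractile apparatus fell as a list. Of 20 such genes, 11 were expressed enough to be tested and all 11 were lower (median log2 fold change -3.02, camera adjusted p = 1.68e-05; adjusted p = 0.564 with an estimated correlation). Adjusted over the list alone 9 of the 11 were lower, against 0 over all genes. Myl4, the atrial essential myosin light chain, stood at 6.17 ± 4.60 CPM in wild type and 0.809 ± 0.469 CPM in knockout libraries, Actc1, cardiac alpha actin, at 35.5 ± 49.2 and 1.22 ± 0.508 CPM, and Tnnt2, cardiac troponin T, at 71.1 ± 57.9 and 10.1 ± 6.70 CPM. Wild type libraries themselves ranged widely, with Tnnt2 at 46.3, 29.6 and 137 CPM. The list median lay at -0.15, -1.59 and 1.92 from the wild type mean in wild type replicates 1, 2 and 3 and at -2.92, -2.07 and -3.34 in knockout replicates 1, 2 and 3, of which the last pair also had the low trophoblast medians.

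Regulators of heart formation gave no called list. The same libraries held maternal transcripts, so the value of a gene in these lists need not come from the heart. Tbx5, needed for the atria and the left ventricle, stood at 7.47 ± 7.32 CPM in wild type and 0.871 ± 0.435 CPM in knockout libraries, and Tbx3, of the conduction system, at 83.7 ± 13.9 and 165 ± 24.98 CPM. Over 12 tested cardiac transcription factors the median was -0.95 (camera adjusted p = 0.178), with 3 lower and 1 higher adjusted over the list alone and 0 over all genes. The cardiac progenitor list had a median of -0.24 (adjusted p = 0.142), and the second heart field list, with Six2 at 7.03 ± 9.53 and 0.207 ± 0.0708 CPM and Foxc1 at 6.22 ± 5.53 and 0.637 ± 0.443 CPM, a median of -0.62 (adjusted p = 0.130). In each of these 2 lists, 2 members were lower adjusted over the list alone and 0 over all genes. Calcium handling and hormone genes had a median of -0.73 (adjusted p = 0.436), with the calcium channel gene Cacna1c at 14.2 ± 6.68 and 1.31 ± 1.16 CPM. Endocardial and cushion genes had a median of -0.64 (adjusted p = 0.265), with Bmp2 at 139 ± 45.1 and 317 ± 62.01 CPM and Tbx2 at 4.90 ± 4.34 and 0.737 ± 0.350 CPM, and epicardial genes one of -0.68 (adjusted p = 0.684). These last 3 lists had 0 members past the threshold over all genes or adjusted over the list alone. Without wild type replicate 2 the second heart field, calcium handling, endocardial and epicardial lists were called lower (adjusted p = 0.0162, 0.0143, 0.0155 and 0.0283, the lowest over their alternatives, with 0.846, 0.829, 0.834 and 0.949 as the highest).

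Endothelial genes rose. The list had a median of 0.78 over 21 genes, 18 of them higher (camera adjusted p = 1.62e-05, and adjusted p = 0.564 with an estimated correlation), with 7 higher adjusted over the list alone and 0 over all genes. Its median lay at 0.565, 0.879 and 0.976 from the wild type mean in knockout replicates 1, 2 and 3. In wild type replicates 1, 2 and 3 it lay at -0.0659, 0.283 and -0.166. Emcn, endomucin of veins and capillaries, stood at 33.5 ± 4.83 CPM in wild type and 75.95 ± 16.3 CPM in knockout libraries, and Ramp2, the co-receptor of the adrenomedullin receptor, at 44.05 ± 2.74 and 80.5 ± 14.5 CPM. Primitive erythroid genes fell (median -2.20, 16 of 16 lower, adjusted p = 3.23e-07; adjusted p = 0.564 with an estimated correlation), with 1 lower adjusted over the list alone and 0 over all genes. Alas2, the first enzyme of haem synthesis in red cells, stood at 93.9 ± 24.7 and 29.7 ± 7.88 CPM, and Slc4a1, the anion exchanger band 3, at 31.4 ± 27.1 and 2.09 ± 2.61 CPM. The erythroid median lay at -1.30 in knockout replicate 1 and at -3.82 and -3.21 in replicates 2 and 3. Haematopoietic progenitor and macrophage genes had a median of 0.48 and a mean of -0.14 and were not called (test direction upward, adjusted p = 0.0567), with 6 higher and 2 lower of 20 adjusted over the list alone, 0 over all genes, and Kit at 61.8 ± 11.03 and 179 ± 60.03 CPM. That list passed without wild type replicate 1 (adjusted p = 0.0429), without knockout replicate 1 (adjusted p = 0.0262) and with either other filter on low counts (adjusted p = 0.013 and 5.1e-05), within a range of 5.1e-05 to 0.564.

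Genes of the nervous system fell. The neural progenitor list, of which 10 of 24 genes were tested, had a median of -3.75 with all 10 lower (camera adjusted p = 1.68e-05; adjusted p = 0.564 with an estimated correlation), 6 of them lower adjusted over the list alone and 0 over all genes. Pax6, a regulator of eye and forebrain, stood at 13.4 ± 6.99 CPM in wild type and 2.76 ± 0.532 CPM in knockout libraries. The list of differentiating neurons had a median of -3.54 with all 9 tested members lower (adjusted p = 0.00726; adjusted p = 0.564 with an estimated correlation), 2 adjusted over the list alone and 0 over all genes. Elavl4, an RNA-binding protein of neurons, was read at 112 CPM in wild type replicate 3 against 6.99 and 3.66 CPM in replicates 1 and 2, with a knockout mean of 0.463 ± 0.432 CPM. Without wild type replicate 3 the neuronal list was not called (adjusted p = 0.0953, range over the alternatives 7.18e-11 to 0.564). The neural progenitor median lay at -1.84, -4.42 and -4.43 in knockout replicates 1, 2 and 3 and at 0.104, -1.96 and 1.31 in wild type replicates 1, 2 and 3. The neuronal median lay at -1.43, -3.81 and -2.16 in the knockout and at -0.865, -2.04 and 3.21 in the wild type replicates. In both lists wild type replicate 2 thus lay below knockout replicate 1.

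Further lists of the embryo body fell as well. Skeletal myogenesis genes had a median of -3.33 (camera adjusted p = 0.0226), surface ectoderm genes of -1.13 (adjusted p = 0.0132), Hox genes of groups 1 to 5 of -1.40 (adjusted p = 0.0226), gut and hepatic endoderm genes of -1.43 (adjusted p = 0.0251) and paraxial mesoderm genes of -1.42 (adjusted p = 0.0413). With an estimated correlation each of the 5 had adjusted p = 0.564, and 0 members of any passed over all genes. Adjusted over the list alone, 4 of 8 myogenic genes were lower and 1 higher, 1 of 11 surface ectoderm genes was lower, 2 of 11 paraxial genes were lower and 1 higher, and none of the Hox or gut genes passed. Acta1, skeletal alpha actin, stood at 54.0 ± 55.8 CPM in wild type and 0.475 ± 0.367 CPM in knockout libraries. It was read at 48.8, 0.975 and 112 CPM in wild type replicates 1, 2 and 3, so replicate 2 lay near knockout replicate 1, at 0.863 CPM. Des, desmin, an intermediate filament of all muscle types, stood at 1197 ± 283 CPM in wild type and 3027 ± 878 CPM in knockout libraries. Des also stands on the decidual list, so its value need not come from embryonic muscle. Perp, a desmosome gene of stratified epithelia, stood at 38.2 ± 2.48 and 7.49 ± 3.32 CPM, Hoxa5 at 7.19 ± 8.13 and 0.637 ± 0.534 CPM, and Sox17, of endoderm and also of endothelium, at 63.2 ± 25.3 and 108 ± 18.3 CPM. In knockout replicates 1, 2 and 3 the gut median lay at 0.17, -4.31 and -4.42 from the wild type mean. The surface ectoderm median lay at 0.28, -3.90 and -2.64. Both were thus low in the 2 libraries with the low trophoblast medians and above the wild type mean in replicate 1. The medians of the myogenic, Hox and paraxial lists lay at -2.30, -4.97 and -3.13, at -0.48, -1.94 and -0.97 and at -0.18, -1.13 and -1.17 in the same order. Wild type replicate 2 lay at -1.1 for the Hox list and at -0.492 for the paraxial list, below knockout replicate 1 in both. The calls were lost without wild type replicate 3 for the myogenic (adjusted p = 0.133), Hox (0.265) and paraxial (0.162) lists, without wild type replicate 1 for the Hox (0.095) and paraxial (0.0868) lists and without wild type replicate 2 for the gut list (0.0917). The paraxial call was also lost with camera on ranks (adjusted p = 0.0744). Over all alternatives the adjusted p ranged from 0.00181 to 0.564, 7.01e-05 to 0.564, 0.000112 to 0.564 and 1.33e-06 to 0.564 for the myogenic, Hox, paraxial and gut lists, and the surface ectoderm, Hox, gut and paraxial calls were also lost with knockout replicate 1 alone (0.587, 0.269, 0.326 and 0.0663).

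Interferon response genes rose, with a median of 1.08 and all 16 tested members higher (camera adjusted p = 1.94e-09; adjusted p = 0.564 with an estimated correlation). Adjusted over the list alone 13 of the 16 were higher, against 0 over all genes. Ifit3, an antiviral protein, stood at 18.1 ± 7.51 CPM in wild type and 49.4 ± 10.9 CPM in knockout libraries, and Ifitm3, which blocks viral entry, at 75.01 ± 11.8 and 167 ± 47.2 CPM. The list median lay at 0.68, 1.24 and 1.22 in knockout replicates 1, 2 and 3. In wild type replicates 1, 2 and 3 it lay at 0.0393, 0.336 and -0.364. It was thus highest in wild type replicate 2 and lowest in wild type replicate 3, the reverse of the sarcomere and neural progenitor medians. Immediate early genes rose (median 0.44, 15 of 20 higher, adjusted p = 0.00289; adjusted p = 0.564 with an estimated correlation), with 3 adjusted over the list alone and 0 over all genes, and with Junb at 125 ± 35.1 and 289.9 ± 72.8 CPM and Klf4 at 142 ± 33.1 and 291 ± 57.2 CPM. Without wild type replicate 3 that call was lost (adjusted p = 0.0559, range over the alternatives 0.000394 to 0.564).

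**Figure D3:**
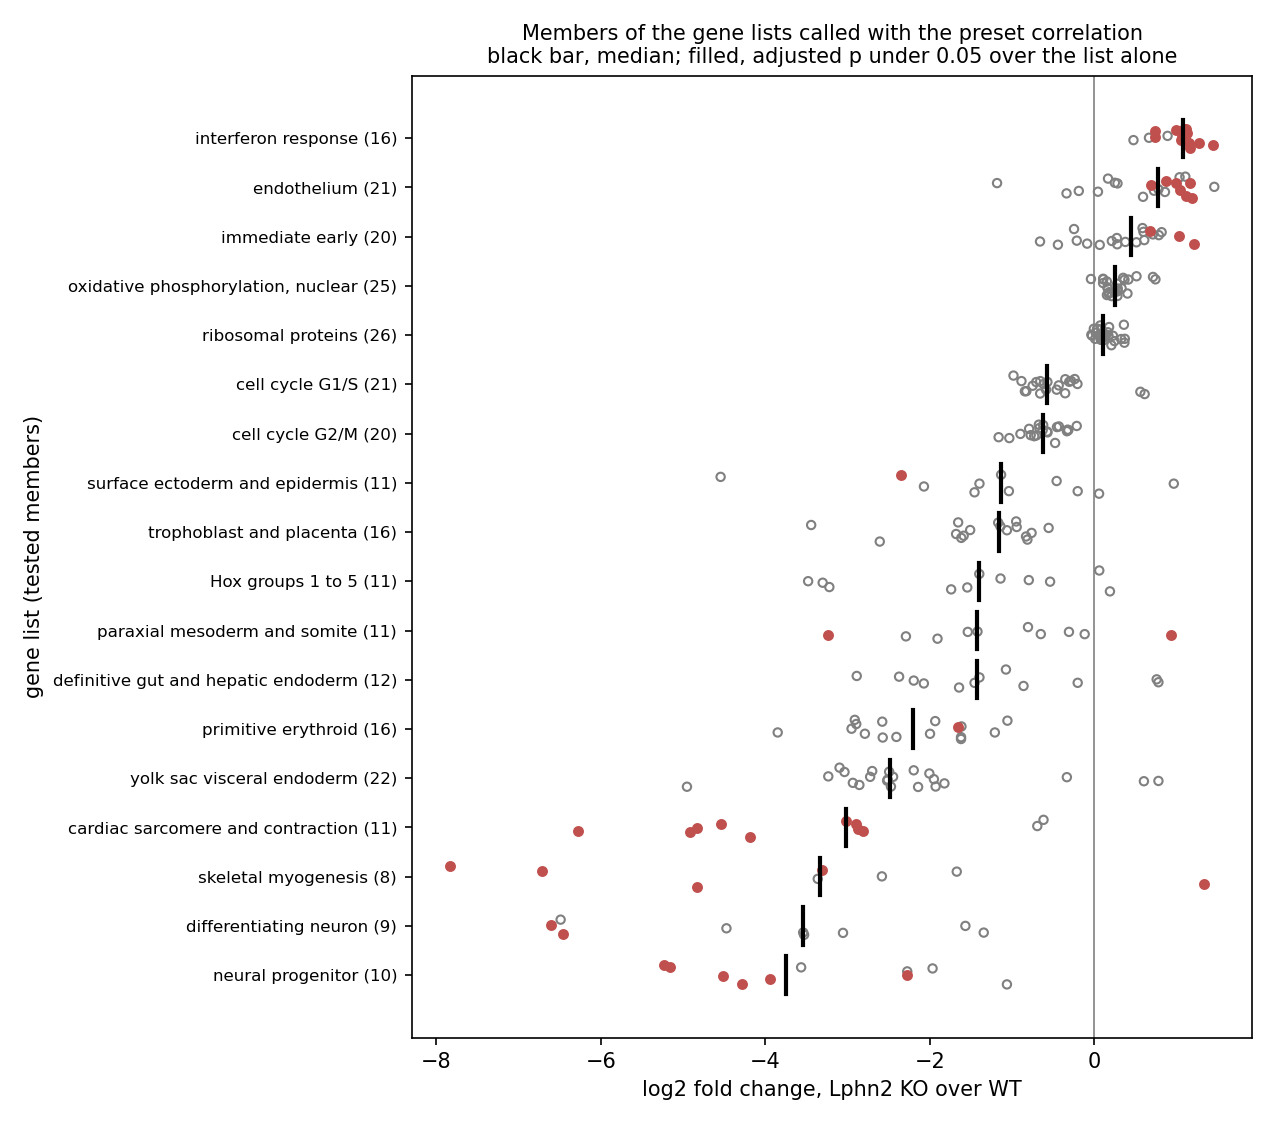
Log2 fold change (knockout over wild type) of each tested member of the 18 lists that passed camera with its preset correlation, with filled points for members past an adjusted p of 0.05 over the list alone and black bars for list medians; Pax9, at 0 counts in every knockout library, is not drawn. All 16 interferon genes lie above 0 and all 11 sarcomere genes below it.

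Nuclear genes of oxidative phosphorylation rose by a median of 0.25 with 24 of 25 higher (camera adjusted p = 0.000560; adjusted p = 0.564 with an estimated correlation), among them Ndufa4, at 60.8 ± 11.2 CPM in wild type and 102 ± 5.47 CPM in knockout libraries. Ribosomal protein genes rose by a median of 0.11 with 23 of 26 higher (adjusted p = 0.0398; adjusted p = 0.564 with an estimated correlation). Cell cycle genes fell, those of the G2/M phases with a median of -0.62 and all 20 lower (adjusted p = 0.000159) and those of the G1/S transition with one of -0.57 and 19 of 21 lower (adjusted p = 0.00346), with adjusted p = 0.564 for both with an estimated correlation. Cdc20, which activates the anaphase-promoting complex, stood at 32.4 ± 7.31 and 19.9 ± 2.24 CPM, and Mcm7, of the replicative helicase, at 48.9 ± 14.2 and 26.5 ± 6.62 CPM. None of the members of these 4 lists passed over all genes or adjusted over the list alone. The G2/M median lay at -0.495 in wild type replicate 2, below the -0.207 of knockout replicate 1. For the G1/S list these 2 libraries lay at -0.359 and 0.0903. All 4 calls were lost with knockout replicate 1 alone against wild type, where the G1/S list turned upward (adjusted p = 0.162, 0.134, 0.312 and 0.512 in the order given), and the ribosomal call also without wild type replicate 3 (adjusted p = 0.232). Over all alternatives the adjusted p ranged from 5.49e-05, 0.00738, 5.54e-06 and 5.15e-05 to 0.564 in each.

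The remaining lists were not called, though some were under single alternatives. Hox genes of groups 6 to 13 had a median of -0.07 and a mean of -0.43 with an upward test direction (camera adjusted p = 0.684), and 7 were higher and 1 lower of 17 adjusted over the list alone, with Hoxd9 at 21.7 ± 6.38 CPM in wild type and 49.2 ± 15.2 CPM in knockout libraries. Cholesterol synthesis genes differed in both directions by the mixed test of fry (adjusted p = 0.000148), with Mvk, mevalonate kinase, at 87.03 ± 22.6 and 31.8 ± 1.18 CPM, and had adjusted p = 0.919 with camera and 1 in each direction adjusted over the list alone. BMP and TGF-beta genes had 3 higher of 14 adjusted over the list alone (camera adjusted p = 0.308), with Id2 at 182 ± 17.5 and 351 ± 58.8 CPM. Notch genes (adjusted p = 0.919) had 2 higher and 1 lower, Wnt targets (0.315) 1 lower, intermediate mesoderm (0.265) 1 in each direction, and p53 targets 2 lower adjusted over the list alone. The p53 list had a median of 0.15 and a mean of -0.05 with an upward test direction (adjusted p = 0.455), and the unfolded protein list a median of 0.0044 and a mean of -0.013 with an upward direction (adjusted p = 0.684) and 0 members past it. Adjusted over the list alone, 0 members passed for limb mesoderm (camera adjusted p = 0.114), neural crest (0.308), extracellular matrix (0.338), hypoxia (0.919), glycolysis (0.392) and heat shock (0.363), and 0 members of any of these uncalled lists passed over all genes. The neural crest list was called lower without wild type replicate 2 (adjusted p = 7.01e-05) and without knockout replicate 2 (0.0393) or 3 (0.0163), with no filter (0.0117) and with knockout replicate 1 alone (0.0472), within a range of 7.01e-05 to 0.851. Hox genes of groups 6 to 13 were called higher with a filter of at least 5 CPM in 3 libraries (adjusted p = 0.000398, range over the alternatives 0.000398 to 0.949). Their test direction turned downward without knockout replicate 1. Heat shock genes were called lower without knockout replicate 1 (adjusted p = 0.0342) and higher with it alone (0.0323), within a range of 0.0323 to 0.990. Lower calls were gained by limb mesoderm without knockout replicate 1 (adjusted p = 0.0386, range over the alternatives 0.0386 to 0.844) and by intermediate mesoderm with no filter (adjusted p = 0.0117, range 0.0117 to 0.564). Without wild type replicate 2 they were gained by extracellular matrix (adjusted p = 0.0283, range 0.0283 to 0.932) and Wnt targets (adjusted p = 0.0462, range 0.0462 to 0.891).

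The sex-linked genes split both groups. Ddx3y on the Y chromosome was read at 15.7, 17.1 and 0.026 CPM in wild type replicates 1, 2 and 3 and at 12.8, 0.467 and 0.071 CPM in knockout replicates 1, 2 and 3. Xist, expressed from the inactive X chromosome, was read in every library, at 494, 307 and 839.8 CPM and at 400.1, 646 and 682 CPM in the same order. The libraries with high Ddx3y thus held Xist as well. In wild type replicates 1 and 2 and knockout replicate 1, Eif2s3y was read at 2.39, 1.77 and 0.902 CPM, Kdm5d at 1.16, 0.548 and 0.510 CPM and Uty at 1.92, 1.28 and 0.863 CPM. In the other libraries these 3 genes had 0 counts, except Uty at 0.20 CPM in knockout replicate 2. Usp9y was read at 0.061 CPM in wild type replicate 2 and had 0 counts elsewhere. Zfy1 and Sry had 0 counts in all 6 libraries. The Y-linked list was not called (4 tested, median -1.51, camera adjusted p = 0.338), except as lower without wild type replicate 3 (adjusted p = 0.036, range over the alternatives 0.036 to 0.835). Tsix, antisense to Xist and not separable from it if tags were counted without regard to strand, was read at 162, 99.8 and 236 CPM in wild type and at 109, 175 and 188 CPM in knockout replicates 1, 2 and 3. Its means were 166 ± 68.05 and 157 ± 42.4 CPM.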

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

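Counts divided by their common divisor, removal of Rn45s, 1 symbol per identical set and knockout replicate 1 alone were tried only after seeing the data. DESeq2 called 439 genes higher and 488 lower, 300 and 473 of them by at least 2-fold, and gave Adgrl2 a log2 fold change of -1.79 past the threshold; the cause was not tested. With 1 symbol per identical set 0 genes were lower and 0 lower by at least 2-fold, since identical symbols each count in the adjustment. With knockout replicate 1 alone, assumed to vary like wild type, 0 genes were lower (0 by at least 2-fold) and 7 lists were lower, with fewer samples. With the replicate number as a block, 0 genes were lower and 0 by at least 2-fold, and the paraxial mesoderm and ribosomal lists did not pass (adjusted p = 0.0874, range over the alternatives 0.000112 to 0.564, and 0.0504, range 0.00738 to 0.564); it changed no other call of a list. Same-numbered libraries deviated together with r of 0.127, -0.0238 and 0.0706, so the numbers do not pair the samples. The deviations of wild type replicate 2 had r of 0.0186, -0.0238 and -0.0011 with those of knockout replicates 1, 2 and 3, so they matched none of them. The filter of at least 5 CPM left 8 lower lists from fewer genes, and camera with an estimated correlation, and fry by direction, called 0 lists higher and 0 lower.

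Leaving out each library in turn, genes higher ranged from 0 to 252, lower from 0 to 466, higher by at least 2-fold from 0 to 230 and lower by at least 2-fold from 0 to 456. All the highest values came without knockout replicate 1, and 0 lower genes were left without wild type replicate 1, knockout replicate 2 or knockout replicate 3. Lists higher ranged from 3 to 6 and lower from 10 (without wild type replicate 3) to 20 (without wild type replicate 2), and the log2 fold change of Adgrl2 from -2.36 to -1.45. Signs turned among genes that had not passed: Aldh1a2 ranged from -1.43 to 0.21, Tsix from -0.325 to 0.26, Xist from -0.20 to 0.52, Adgrl1 from -0.78 to 0.40, Flrt2 from -1.15 to 0.20 and Tenm3 from -1.17 to 0.0011. Limma-voom turned Uty to 0.33 and Ddx3y to 0.52, and knockout replicate 1 alone turned Ddx3y to 0.25 and Xist to -0.42; the causes were not tested. Of the other values of named genes, 1635 kept their direction and side of the threshold, 91 passed it newly and 23 lost it.

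The other scaling factors, no filter, removal of Rn45s and removal of X, Y, extraembryonic and decidual genes left 7 lower genes, and library size alone and the common divisor left 6. Simulated 2-fold changes were called in 0 of 67 genes, in a single draw with few genes changed. The edgeR test thus had little power for single-gene changes of that size in that setting.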

Other observations

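The 7 lists in this paragraph and the next were written after the results above had been seen, and the tests of genotype in knockout replicate 1 and of a larger share of the same maternal tissue were also chosen after the result was seen. Genes of natural killer cells, which populate the decidua of pregnancy, rose as a list, with a median log2 fold change of 1.37 and all 20 members higher (camera adjusted p = 2.41e-10; adjusted p = 0.314 with an estimated correlation). Adjusted over the list alone 11 were higher, against 0 over all genes. The list median lay at 0.0862, 0.582 and -0.585 from the wild type mean in wild type replicates 1, 2 and 3. In knockout replicates 1, 2 and 3 it lay at 1.06, 1.92 and 1.51. Members here and below were named after their values were seen. The granzyme gene Gzmd stood at 352 ± 162 CPM in wild type and 1016 ± 295 CPM in knockout libraries, Gzmf at 349 ± 168 and 1053 ± 337 CPM, and Il2rb, a receptor chain for interleukins 2 and 15, at 121 ± 48.5 and 272 ± 43.1 CPM; granzymes D, F and G are close paralogs that can share reads. Genes of antigen presentation rose (median 0.83, 16 of 17 higher, adjusted p = 5.91e-05; adjusted p = 0.331 with an estimated correlation), with 5 higher and 1 lower adjusted over the list alone and 0 over all genes, and with B2m at 239 ± 95.2 and 535 ± 145 CPM. GTPases and chemokines induced by interferon gamma rose too (median 0.94, 14 of 16 higher, adjusted p = 8.64e-07; adjusted p = 0.314 with an estimated correlation), with 8 higher adjusted over the list alone and 0 over all genes, and with Iigp1 at 25.4 ± 5.70 and 65.6 ± 20.9 CPM.

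Imprinted and oncofoetal genes fell (median -1.80, 19 of 19 lower, adjusted p = 8.16e-07; adjusted p = 0.314 with an estimated correlation). H19 was read at 3180.1, 4118 and 2623 CPM in wild type replicates 1 to 3 and at 2659, 79.5 and 107 CPM in knockout replicates 1 to 3. Uterine and glandular epithelium genes fell (median -1.13, 10 of 10 lower, adjusted p = 0.000300; adjusted p = 0.314 with an estimated correlation), and 0 members of either list passed adjusted over the list alone or over all genes. The uterine epithelium median lay at -0.39, -2.70 and -2.08 from the wild type mean in knockout replicates 1, 2 and 3. Of its members, Foxa2 and Spink1 also stand on the gut list and Cldn4 on the surface ectoderm list. Neutrophil genes (median -0.66, adjusted p = 0.795) and uterine smooth muscle genes (-2.10, adjusted p = 0.454) were not called, each with 1 higher member adjusted over the list alone and 0 over all genes. The smooth muscle median lay at 2.33, -1.55 and -1.02 from the wild type mean in wild type replicates 1, 2 and 3 and at -0.97, -0.75 and -0.81 in knockout replicates 1, 2 and 3. The lower value of the knockout group thus rests on wild type replicate 1. Myh11, smooth muscle myosin, was read at 52.5 CPM in wild type replicate 1 and at no more than 1.71 CPM in any other library.

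Embryonic and trophoblast transcripts lay near the floor in knockout replicates 2 and 3. The data argue against lower depth: after thinning all libraries to 14476809 counts, 75 genes of the sarcomere, erythroid, yolk sac, neural progenitor and trophoblast lists still differed by a median of -3.743 between these 2 libraries and the other 4, against -4.199 unthinned. The foetal list, tested as a prediction of less conceptus tissue in these 2 libraries, had a median difference of -4.563, with 15 of 19 genes below every other library, as such a shortage would give, and 1 of its members also stood in another list; it would not by itself lower genes of the mother, so it does not account for the lower uterine epithelium medians (-2.70 and -2.08) as far as those transcripts are maternal. In knockout replicate 1 the 75 genes had a median of -0.9131 from the wild type mean, with 36 below every wild type library, and the foetal list -0.406. The 5 lists differed there, with medians of -2.92 (sarcomere), -1.3 (erythroid), -0.928 (yolk sac), -1.84 (neural progenitor) and 0.549 (trophoblast). The sarcomere median was -2.07 in knockout replicate 2 and -3.34 in replicate 3, so its fall was not confined to these 2 libraries. A smaller or absent embryo in the tissue collected is therefore a candidate explanation for the embryonic and trophoblast genes, and whether it came from dissection or from genotype cannot be told apart, because 1 library cannot decide and the labels do not describe the dissection.

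The interferon median lay above the wild type mean in all 3 knockout libraries, with 13 of 16 members above every wild type library in each. Prl8a2 and Erv3, 2 abundant decidual transcripts, lay below every wild type library in all 3 but did not pass over all genes. The decidual list as a whole had no called direction (camera adjusted p = 0.454). A few genes taking most of the counts would not account for the higher interferon median. The 20 most abundant genes held 24.6% of wild type and 21.4% of knockout counts. Without them, and with library size as the only scaling, that median stayed at 1.036 against 1.08. The lower decidual transcripts were not tested in this way. A larger share of the same maternal tissue would raise genes expressed only there alike. Over the decidual list, Cochran's Q over its degrees of freedom was 11.73, with 4 of 14 genes above 1 and 5 below -1 on the log2 scale. Cryab, Des and Hand2 of that list also stand on lists of the embryo and could diverge with less embryo, so Q cannot decide this. A larger share would not by itself lower Prl8a2 and Erv3, as far as these are maternal. More natural killer cells in the maternal tissue stay open as a hypothesis: the list rose by a median of 1.369, with 14 of 20 genes above every wild type library in all knockout libraries and 0 members shared with the lists fixed in advance, but its unadjusted camera test with an estimated correlation did not pass (0.135), so this cannot be told apart from another change in the maternal cells. Genotype and maternal state were not separated by the design, and an effect of the knockout itself is untested.

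Adgrl2 was lower in all 3 knockout libraries, by a log2 fold change of -1.78. This value lies at percentile 47.71 among 109 tested genes of the cardiac, neural, somite, neural crest, limb and gut lists, whose median was -1.54, so less embryonic RNA may account for it. Loss of the transcript by the deletion would place the gene low among these in knockout replicate 1, where it stood at percentile 40.37, at -0.98 from the wild type mean against an embryonic median of -0.67. Since this is 1 library and the deleted part is unknown, a loss of the transcript cannot be told apart from less embryonic RNA.

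The 6 libraries can be split into 3 and 3 in 10 ways, so no share of splits can lie under 0.1. Which side of another split is the higher one is arbitrary, so the larger of its 2 directions was set against each real count. The real split gave 7 lower genes, 7 of them by at least 2-fold, and the highest of the others gave 0, so 1 of 10 splits reached that count. For higher genes, and for those higher by at least 2-fold, the real split and every other gave 0, which all 10 reach. For lists, the real split gave 5 higher and 13 lower, reached in this way by 6 and by 3 of the 10 splits, with 14 as the highest other in either; for the 5 higher lists, the smaller real direction is thus set against the larger one of each other split. The split of wild type replicates 1 and 3 with knockout replicate 1 against the rest, which keeps knockout replicates 2 and 3 together and apart from 2 of the 3 wild type libraries, gave 14 lists in 1 direction and 4 in the other. With knockout replicate 3 in place of 1 it gave 13 and 5, and with knockout replicate 2 it gave 12 and 4, though both part knockout replicates 2 and 3. Wild type replicate 1 with knockout replicates 2 and 3 gave 11 and 7. The remaining splits gave at most 7 lists in either direction. The counts of lists thus do not set the genotypes apart from other groupings.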
